A study of Mus musculus with 9 samples.

How the data were processed

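CTCF occupancy had been measured by CUT&RUN in 8 libraries of mouse splenic CD8+ T cells, WT or DKO (lacking Tcf1 and Lef1), at 0 h and after 72 h with IL-7 and IL-15, with 2 libraries per group, and 1 IgG library of WT cells at 0 h. Groups and replicate numbers were taken from the sample titles. The files were peak lists in narrowPeak format, called per library by the authors and not on pooled samples, as 1 list belonged to each sample.

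Per the submitters' processing notes, FastQC, Bowtie2 2.2.5 and MACS2 2.1.1 were used and the build was mm9. The control used and the calling thresholds were not given in the sources used here. The last peak of chromosome 1 ended at 197068709, beyond the last gene end of 195291439 on that chromosome in GRCm38. This goes with a build other than GRCm38, though the chromosome length was not compared. The deposited score column is a whole number per peak from the authors' peak caller and entered no comparison. The deposited fold column is the authors' enrichment of each peak over its local background. The deposited −log10 p and −log10 q columns are those of the authors' peak caller. The deposited summit column gives the distance of the summit from the peak start in bp. These values belong to the authors and were used to describe, rank or filter peaks within a list. The fold and −log10 p values also served to infer a relative depth, which was compared between libraries. Every CTCF list held only peaks of fold 4 or more, from 5.13% to 7.38% of the peak numbers were missing from the lists, and the IgG list was not filtered this way, its lowest fold being 1.23.

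Peaks on chromosomes 1 to 19 and X were used. This left out 5 CTCF peaks, all on chromosome Y, and the IgG peaks on the mitochondrial genome. Peaks of the 8 libraries that overlapped by at least 1 bp were merged into consensus regions. A region counted as specific to a group when both its libraries had a peak and neither library of the other group did. Each such count was set beside those of the 2 other pairings of the same 4 libraries. No p-value per region was given for 2 libraries against 2, where the smallest two-sided p is 0.333. Rank percentiles were computed within each list from the authors' −log10 p.

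Peak numbers were compared by exact two-sided permutation within the other factor (36 assignments). Regions tied to genotype over both times were tested by Fisher's exact test with Benjamini-Hochberg adjustment, and the count was recomputed for all 35 splits of the 8 libraries into 4 and 4. Regions found only at 72 h in one genotype were looked up in the other against shared regions matched on rank decile, by a permutation test over regions with 100000 draws. Neighbours within 50 kb were compared with 10000 random draws from regions found in both libraries of the group. Chromosomes were compared by Fisher's exact test with adjustment over 160 tests. Proportions carry exact Clopper-Pearson 95% intervals, which cover counting error only.

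Absolute read depth was not given in the sources used here. Relative depth was inferred from the spacing of fold and −log10 p values in the deposited lists, on the assumption that MACS2 scaled each library to a smaller shared control, and is the number of reads relative to that control. On simulated lists of 20000 peaks at 3 settings the scale was recovered with a largest error of 0.0235%. These lists were made under the same assumption and so do not test it. A list with fewer peaks misses weak sites, so an absent peak shows only that no peak was called. For genotype at 0 h, the overlap step found 200 of 200 planted regions among 39574 simulated regions. For regions found only at 72 h, the permutation test gave a p under 0.05 in 5 of 100 simulations with no difference, on 4000 regions each.

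Regions were named by a rule fixed before the data were examined: per contrast and direction, the 5 specific regions of highest mean rank percentile and the 3 densest 500 kb windows, the 5 highest-ranked regions found in all 8 libraries, and all IgG peaks. Windows are given from the first to the last specific region they hold, with the number of regions found in both libraries of the group between those coordinates. Further X regions found in both genotypes and the regions tied to genotype at both times were added after the values were seen. The planned tests of gene lists near specific regions and of sequence motifs under them were not run, since an annotation and a genome of mm9 were not used here.

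Alternatives tried were peaks with −log10 q of at least 5, lists of equal length, summits within 100 bp, overlap of at least 50% of the shorter peak, all chromosomes kept, a peak in at least 1 library, each library left out in turn, a block by replicate number, windows of 10 and 200 kb, rank-matched draws and unmatched comparison regions. Autosomes alone, splits balanced for time, the pair of 72 h libraries of nearest length, the definition on a single library and other pairings at equal length were added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.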

Results

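Binding of CTCF, a zinc-finger DNA-binding protein found at insulators and at the anchors of chromatin loops, was mapped in mouse CD8+ T cells by CUT&RUN. In this assay a nuclease tethered to an antibody releases the DNA fragments around the bound protein. Naive CD8+ T cells had been sorted from the spleen of wild-type (WT) mice or of mice whose T cells lack Tcf1 and Lef1 (DKO), a pair of related HMG-box transcription factors of the T cell lineage. The cells were profiled at 0 h or after 72 h with the cytokines IL-7 and IL-15, which maintain naive and memory CD8+ T cells. Each of the 4 groups had 2 CTCF libraries, and 1 IgG library of WT cells at 0 h served as a control. The labels do not state that replicates came from separate animals, so p-values of tests over libraries measure the spread between these samples only, which may be technical. Tests over regions, including those by random draws of regions, do not measure the spread between libraries. Sex of the animals was not given in the labels used here. Regions are given as chromosome, start and end in mm9, and no gene is named because no annotation of that build was used here.

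The libraries of naive cells held the most CTCF peaks. WT cells at 0 h had 32587 and 30968 peaks listed, and DKO cells at 0 h had 30309 and 31394. After 72 h, WT cells had 17335 and 26630, and DKO cells had 10339 and 16234. The IgG list held 5 peaks, 2 on chromosome 2 and 3 on the mitochondrial genome, and 0 CTCF peaks overlapped any of them. Those on chromosome 2 were chr2:22442992-22443323 (fold 4.22) and chr2:98506850-98507335 (2.26), and those on the mitochondrial genome spanned 122-6487, 10925-15232 and 15572-16150 (folds 1.23, 1.34 and 1.70). The mean number of peaks used was 31776 ± 1144 (SD, n = 2) in WT at 0 h, 30850.5 ± 766 (n = 2) in DKO at 0 h, 21982.5 ± 6573 (n = 2) in WT at 72 h and 13286.5 ± 4168 (n = 2) in DKO at 72 h. Lists at 72 h were shorter by a mean difference of -13678.8 peaks over both genotypes (exact two-sided permutation test within genotype, n = 4 against 4, p = 0.0556, the smallest p this design allows). The DKO minus WT difference over both times was -4810.75 peaks (exact permutation test within time, n = 4 against 4, p = 0.111). It changed when single libraries were left out, but this also unbalances the times, so these values mix the genotype and time differences. Without DKO 72 h replicates 1 and 2 it was -900.9 and -2865.9. Without WT 0 h replicates 1 and 2 it was -2908.8 and -3448. It was -7558 and -7919 without DKO 0 h replicates 1 and 2, and -7992 without WT 72 h replicate 1. Within a single genotype or time, 2 libraries against 2 cannot go below an exact p of 0.333.

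The authors' median fold enrichment per peak list was 10.1 and 9.78 in WT at 0 h and 10.4 and 10.3 in DKO at 0 h. At 72 h it was 7.89 and 9.06 in WT and 7.03 and 8.05 in DKO. Read totals were not given, but the steps between fold values gave each library's reads relative to a control assumed to be shared by the libraries. This relative depth was 1.88 and 1.96 in WT at 0 h, 1.47 and 1.18 in DKO at 0 h, 2.58 and 1.76 in WT at 72 h, and 2.30 and 2.85 in DKO at 72 h. Under that assumption, the shortest lists did not come from the libraries with the lowest relative depth.

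**Figure D1:**
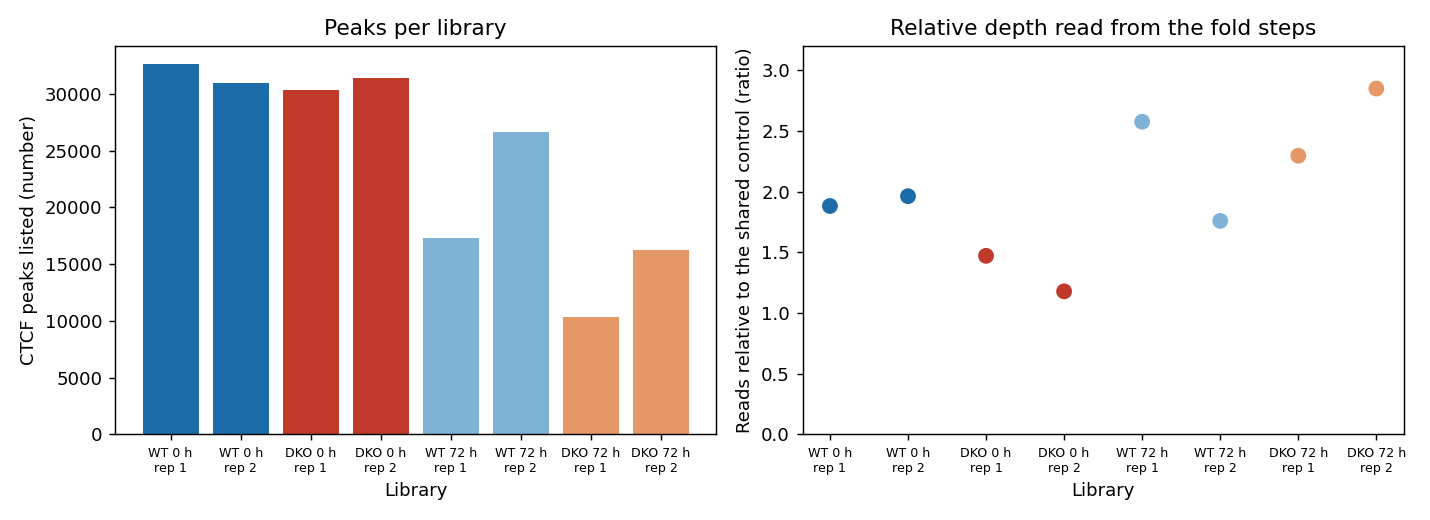
CTCF peaks listed per library (left, number, bars) and reads of each library relative to a control assumed to be shared (right, ratio, points), with 2 replicates per group. The 4 libraries at 0 h hold 30309 to 32587 peaks and those at 72 h hold 10339 to 26630, while relative depth runs from 1.18 to 1.96 at 0 h and from 1.76 to 2.85 at 72 h.

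A core of CTCF sites was found in every library. Merging the peaks of the 8 libraries gave 39574 regions with a median width of 747 bp. Of these, 9591 (24.2%) had a peak in all 8 libraries and 5811 (14.7%) in 1 library. The highest-ranked regions found in all 8 were chr19:5487605-5491667, where fold enrichment ran from 28.3 to 107 between libraries, chr10:57463083-57464093 (21.4 to 84.3), chr2:146783964-146785857 (35.7 to 164), chr4:135475793-135477281 (39.1 to 144) and chr2:173054759-173055928 (19.7 to 82.9). Both replicates held a peak at 28355 regions in WT at 0 h, 27186 in DKO at 0 h, 16714 in WT at 72 h and 9893 in DKO at 72 h.

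Replicates overlapped closely at 0 h and less evenly at 72 h. In WT at 0 h, 88.1% of the peaks of replicate 1 overlapped a peak of replicate 2, and 92.8% in the other direction. In DKO at 0 h these shares were 90.8% and 87.5%. At 72 h nearly all peaks of the shorter list were in the longer list (98.7% in WT, 97.7% in DKO), while 63.8% and 62.0% of the longer list were in the shorter. The base-pair Jaccard index between replicates was 0.741 in WT and 0.704 in DKO at 0 h, and 0.537 and 0.53 at 72 h. With summits within 100 bp in place of overlap by 1 bp, the mean replicate share at 0 h was 74.8% in WT and 70.3% in DKO, against 90.4% and 89.1%, and at 72 h it was 64.9% and 62.8%, against 81.2% and 79.9%.

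Peaks absent from another library were mostly those of low rank. In the weakest decile of WT 0 h replicate 1 peaks, by the authors' p-value, 45.2% were found in WT 0 h replicate 2, 43.0% in DKO replicate 1 and 47.3% in DKO replicate 2 at 0 h. In the fifth decile, 96.6% were found in the other WT 0 h library, against 89.0% and 89.8% in the DKO 0 h libraries. In the strongest decile these shares were 100%, 99.9% and 99.9%. At 72 h, the strongest decile was found at 98.5% and 99.7% in WT and at 92.2% and 97.5% in DKO, and the fifth decile at 40.5% and 77.5% in WT and at 9.36% and 34.7% in DKO.

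**Figure D2:**
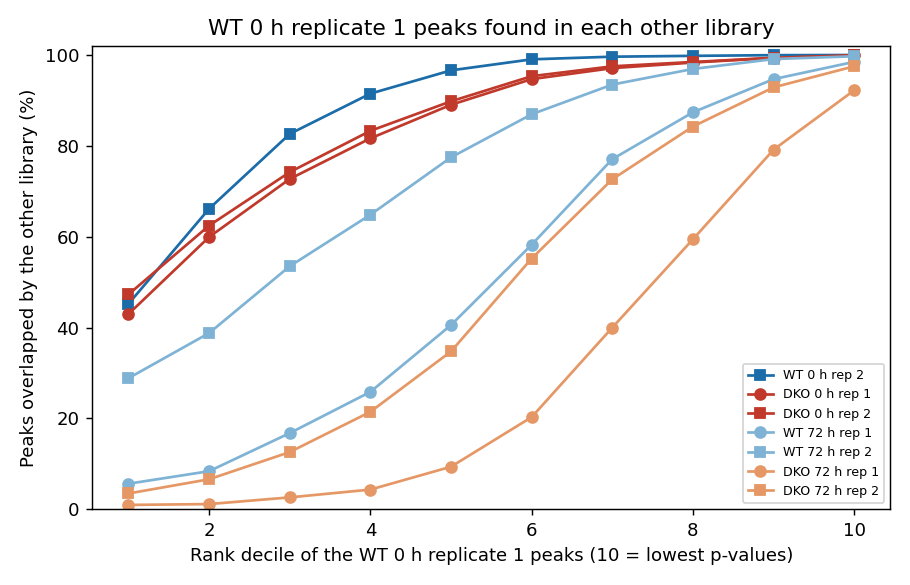
Share of WT 0 h replicate 1 peaks (%, vertical axis) overlapped by each other CTCF library, by rank decile of the authors' p-value (horizontal axis, 10 holds the lowest p-values), with 1 line per library. In the fifth decile the WT 0 h replicate lies at 96.6%, the DKO 0 h libraries at 89.0% and 89.8%, and the 72 h libraries between 9.36% and 77.5%.

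Naive WT and DKO cells were compared to ask where CTCF peaks differ without Tcf1 and Lef1. At 0 h, 1932 regions had a peak in both WT libraries and neither DKO library, which was 6.81% of the regions found in both WT libraries. In the other direction, 1080 regions (3.97%) were found in both DKO libraries and neither WT library. The 2 other ways of pairing these 4 libraries gave 845 and 832 regions over both directions, against 3012 for genotype. Most of these regions ranked low, with a median rank percentile of 23.0 for WT-only and 17.1 for DKO-only regions, and 33 of the 1932 and 3 of the 1080 lay in the top 25% of ranks.

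The highest-ranked WT-only regions at 0 h were chr4:148656261-148657190 (fold 12.8 and 13.4 in the WT libraries), chr18:56606579-56607282 (14.7 and 12.5), chr15:36325539-36326907 (18.6 and 22.4), chr12:29519021-29519847 (6.97 and 6.91) and chr5:63206796-63207403 (13.7 and 12.5). Of these, the regions on chromosomes 18, 15 and 5 also had a peak in both WT libraries at 72 h, and none of the 5 had a peak in a DKO library at 72 h. The strongest DKO-only region was chr1:167788481-167792284, 3804 bp wide, with a fold of 68.8 and 50.4 and a rank percentile of 99.6 and 99.5. It was followed by chr9:63574172-63574999 (fold 23.6 and 23.6), chr4:119593485-119594161 (20.2 and 20.4), chr7:135380588-135382894 (10.6 and 10.8) and chr10:80970543-80971287 (8.12 and 8.60). The region on chromosome 7 had peaks of fold 4.11 and 4.81 in the WT libraries and of 4.32 in DKO replicate 2 at 72 h.

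Genotype-specific regions at 0 h lay near each other more often than random regions of the same group. Neighbours were not counted for the other pairings of these libraries, so the excess is not shown to be particular to genotype. Of the WT-only regions, 35% had another WT-only region within 50 kb, against 19.2% in a permutation test of 10000 random draws (p = 1e-04, the smallest the draws can give), and of the DKO-only regions 23.8% against 11.8% (p = 1e-04). The densest WT-only windows were chr6:98981049-99436526, where 10 of 19 regions were WT-only, chr10:20602476-21056346 (9 of 17) and chr9:116000319-116203807 (9 of 14). The densest DKO-only windows were chr4:119593485-119996416 (9 of 17), chr11:83343766-83542850 (7 of 13) and chr10:80715380-80973477 (6 of 28). With lists shortened to the same 30309 top peaks, WT-only regions numbered 1701 and DKO-only regions 1253, a ratio of 1.36 against 1.79 with the full lists, and the other pairings gave 776 and 753. When a single library had to hold or lack the peak in place of both, the WT-only count was 2957 without WT replicate 1, 3550 without WT replicate 2 and 3067 without DKO replicate 2, and the DKO-only count was 2201, 1627, 2864 and 2258 without WT replicates 1 and 2 and DKO replicates 1 and 2.

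**Figure D3:**
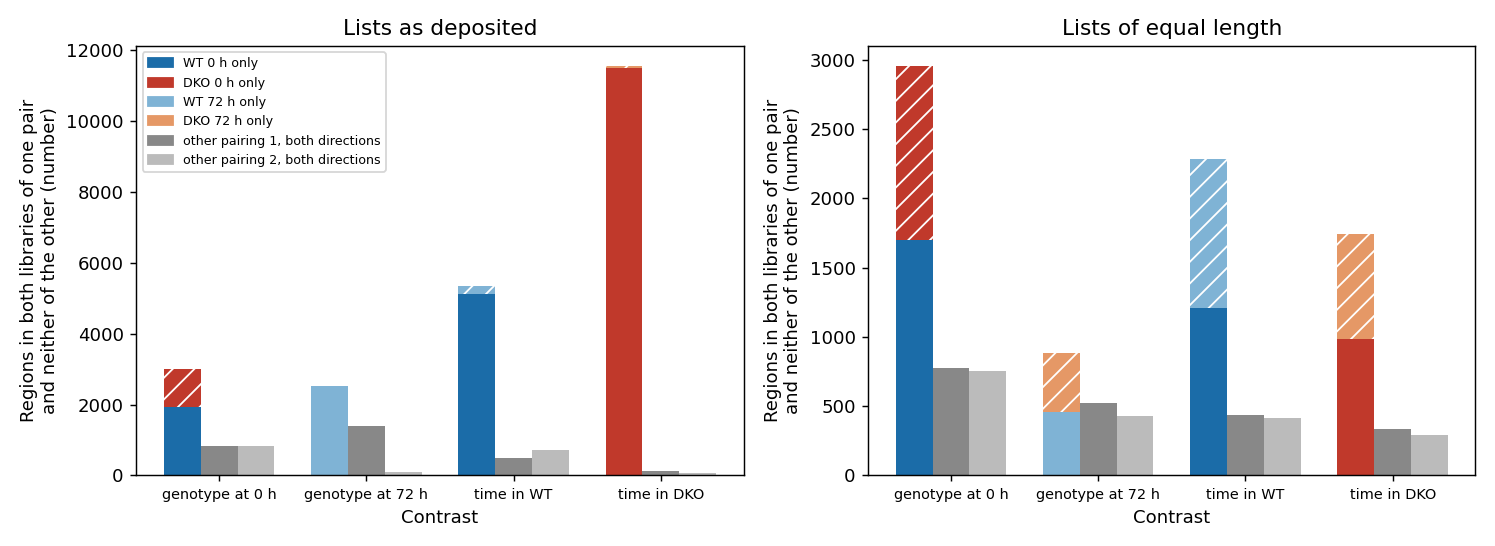
Regions with a peak in both libraries of one group and neither of the other (number), for each contrast, stacked over both directions (coloured bars, the upper direction hatched), beside the totals of the 2 other pairings of the same 4 libraries (grey bars), with the lists as deposited (left) and with lists of equal length (right). The genotype total at 0 h is 3012 against 845 and 832, and at 72 h with equal lengths it is 884 against 525 and 432.

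WT and DKO cells were compared again after 72 h of IL-7 and IL-15. With the lists as deposited, 2521 regions were found in both WT libraries and neither DKO library, and 12 in both DKO libraries and neither WT library. The other pairings of the 4 libraries gave 1399 and 106 regions over both directions, and the lists differed in length by replicate as well as by genotype. With the same 10339 top peaks per library, WT-only regions numbered 461 and DKO-only regions 423, a total of 884 against 525 and 432 for the other pairings. At equal length the genotype pairing thus still gave more regions than the 2 other pairings. With 2 libraries against 2 an exact p cannot go below 0.333, so chance was not excluded. The share of WT-only among specific regions was 52.1%.

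Among WT-only regions at 72 h, the highest-ranked was chr5:148134487-148135733, with a fold of 10.1 and 24.0 in the WT libraries. Both DKO libraries at 0 h had a peak there too (18.3 and 16.1). The next were chr1:138497024-138497699 (14.3 and 22.7), chr13:95745667-95747061 (6.69 and 8.0), chr12:88151195-88152343 (17.9 and 19.8) and chr13:113214201-113215711 (7.13 and 12.2). Of these, the regions on chromosomes 13 and 12 also had a peak in both DKO libraries at 0 h (12.0 and 8.89, 4.24 and 7.63, and 7.91 and 6.81 in the order given), and chr1:138497024-138497699 had none. The DKO-only regions were led by the same chr1:167788481-167792284 region as at 0 h, which held the top peak of both DKO lists at 72 h (fold 39.3 and 59.5), and by chr4:119593485-119594161 (10.6 and 10.7). Next came chr2:118380074-118380677 (5.71 and 8.22), chr10:128100606-128101166 (6.26 and 9.83) and chr7:50720678-50722381 (5.95 and 8.75). The densest WT-only windows were chr11:69696383-70051952 (8 of 16), chr4:154048695-154425112 (8 of 15) and chr1:182286088-182705223 (7 of 12). WT-only regions had a neighbour within 50 kb in 25.6% of cases against 23.2% for random draws (permutation p = 0.0288), a difference that was not past the threshold at 10 kb (p = 0.864) or 200 kb (p = 0.112), and 0 of the 12 DKO-only regions had one. The WT-only count was 10218 without WT replicate 1 and 6891 without DKO replicate 2, and the DKO-only count was 208 without WT replicate 2 and 157 without DKO replicate 1.

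Regions with the same genotype difference at both times were few and favoured WT. A peak in all 4 WT and no DKO library was found at 197 regions, and the reverse at 5. The leading WT-only regions were chr1:138497024-138497699 (fold 19.9 and 19.6 at 0 h, 14.3 and 22.7 at 72 h), chr2:127753239-127754157 (15.9, 9.07, 9.18 and 18.2), chr19:29528186-29529154 (15.6, 11.1, 8.50 and 9.41), chr5:108269411-108270277 (13.9, 14.9, 7.63 and 12.9) and chr19:3730853-3731869 (22.3, 23.8, 11 and 18.7). The 5 DKO-only regions were chr1:167788481-167792284, chr4:119593485-119594161, chr10:128100606-128101166, chr6:108580572-108581472 (fold 10.1 and 8.70 at 0 h, 5.18 and 7.39 at 72 h) and chr16:24165832-24166476 (4.58, 4.74, 4.90 and 5.41).

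A two-sided Fisher's exact test per region gave 202 regions with an unadjusted p under 0.05, each at 0.0286, the smallest that 4 libraries against 4 allow. After Benjamini-Hochberg adjustment over 39574 regions, 0 had a p under 0.05. With lists of 10339 peaks each, 54 regions were WT-only and 30 DKO-only, so the WT excess was smaller at equal length. The WT-only count was 315 without DKO 0 h replicate 2 and 738 without WT 72 h replicate 1, and the DKO-only count was 9 without WT 72 h replicate 2 and 15 without DKO 72 h replicate 1.

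The 0 h regions specific to a genotype were also followed to 72 h. Of the 1932 WT-only regions, 12.4% and 40.6% had a peak in the WT 72 h libraries, and 0.518% and 2.43% in the DKO 72 h libraries. Of the 1080 DKO-only regions, 3.70% and 17.1% had a peak in WT and 1.85% and 5.46% in DKO at 72 h. Regions found in all 4 libraries at 0 h had a peak at 72 h in 65.2% and 86.9% of cases in WT and in 40.9% and 62.7% in DKO. In the pair of 72 h libraries of nearest list length, WT replicate 1 and DKO replicate 2, the peak was in WT alone at 211 and in DKO alone at 19 of the 0 h WT-only regions. Of the 0 h DKO-only regions, these numbers were 14 and 33 (odds ratio 26.2, 95% interval 12.0 to 57.2; Fisher's exact test over regions, which are not independent replicates, p = 1.33e-18).

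Comparison of WT cells at 0 h and 72 h asked how CTCF peaks differ after culture with cytokines. Since the sex of the animals was not given, any difference in sex between the times would enter every comparison of 0 h with 72 h. In WT cells, 5126 regions were found in both libraries at 0 h and neither at 72 h, and 228 in both at 72 h and neither at 0 h. The other pairings of these libraries gave 495 and 710 regions over both directions. Regions found only at 0 h ranked low (median percentile 23.9), and 46 of 5126 lay in the top 25% of ranks. With lists of 17335 peaks each, 1211 regions were found only at 0 h and 1075 only at 72 h, a total of 2286 against 436 and 418 for the other pairings, and the 0 h share of the specific regions was 53.0%.

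The highest-ranked WT regions found only at 0 h were chr10:18781672-18783057 (fold 12.0 and 9.62), chr3:115518154-115519327 (8.58 and 7.33), chr17:8176207-8176523 (39.2 and 29.4), chr8:13785174-13786680 (5.57 and 9.46) and chr12:45369348-45370752 (17.9 and 16.9). All 5 had peaks in both DKO libraries at 0 h, and chr17:8176207-8176523 had one in DKO replicate 1 at 72 h. The densest windows were chr9:32295011-32769177 (16 of 28 regions), chr3:130512511-131006460 (14 of 30) and chr8:86253289-86730954 (14 of 37), and 50.2% of the regions had a neighbour within 50 kb against 41.3% for random draws (permutation p = 1e-04, the smallest possible). The count at 0 h was 8101 without WT 0 h replicate 2 and 11905 without WT 72 h replicate 2, and the count at 72 h was 357 without WT 0 h replicate 1 and 1627 without WT 72 h replicate 1.

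Regions found in WT only at 72 h were led by a cluster on the X chromosome. Within chrX:47903051-47976746, 15 of the 17 regions of WT cells at 72 h had no peak in WT cells at 0 h. The strongest were chrX:47955441-47956710 (fold 36.4 and 51.8 in WT), chrX:47967483-47968386 (27.1 and 43.0), chrX:47952692-47953850 (32.9 and 37.1) and chrX:47964800-47965771 (21.6 and 33.0), and all of these also had a peak in both DKO libraries at 72 h and in no library at 0 h. The fifth was chr15:61239614-61240510 (13.1 and 14.2). A separate X window, chrX:72975031-73004678, held 6 regions in both WT libraries at 72 h, all 6 without a peak in WT at 0 h, and chr8:89331928-89412348 held 4 of 4 such regions. The X chromosome carried 33 of the 228 regions (14.5%), against 2.51% of the other regions (Fisher's exact test, adjusted p = 2.10e-13 over 160 tests). Of the 33, the X windows above held 15 and 6, so the regions are not independent and the p-value is too small. Leaving the X chromosome out gave 195 regions. A neighbour within 50 kb was found for 22.4% of the 228 regions, against 2.45% for random draws (permutation p = 1e-04).

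**Figure D4:**
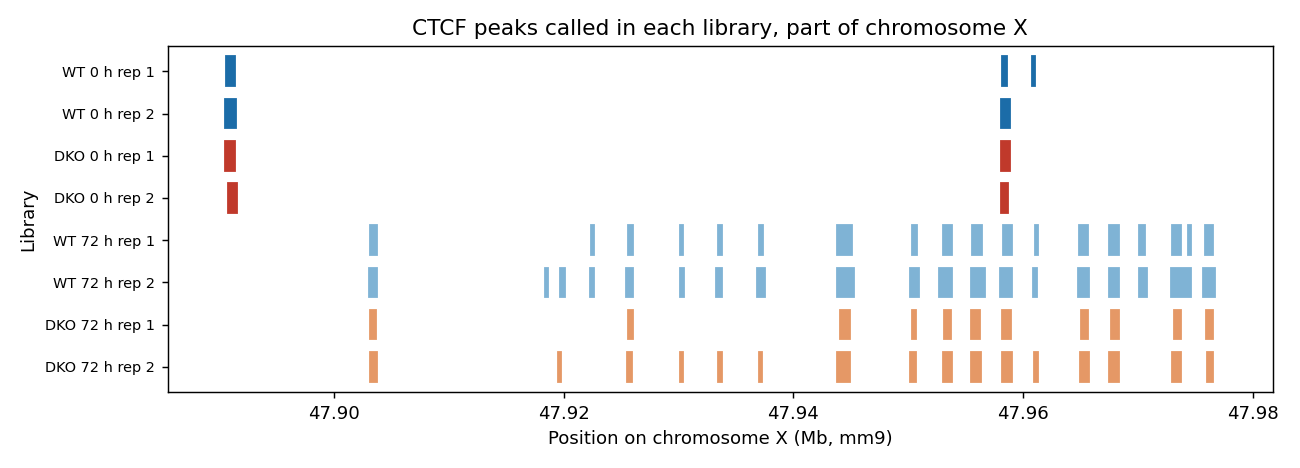
CTCF peaks (coloured boxes, drawn to scale) of each of the 8 libraries along part of the X chromosome, with position in Mb of mm9 on the horizontal axis. The window holds 3, 2, 2 and 2 peaks in the WT and DKO libraries at 0 h, 18 and 19 in WT at 72 h, and 11 and 16 in DKO at 72 h.

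In DKO cells, 11501 regions (42.3% of those found in both DKO libraries at 0 h) had a peak in both libraries at 0 h and neither at 72 h, and 46 were found only at 72 h. The other pairings gave 118 and 58 regions. With lists of 10339 peaks, 987 regions were found only at 0 h and 754 only at 72 h, a total of 1741 against 332 and 292 for the other pairings, and the 0 h share of the specific regions was 56.7%. The difference between DKO and WT in the size of the time contrast was not tested.

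The leading DKO regions found only at 0 h were chr5:121062277-121063707 (fold 14.8 and 8.26), chr8:13785174-13786680 (12.5 and 11.8), chr7:134351778-134353204 (8.61 and 10.2), chr8:20019976-20020814 (12.3 and 11.4) and chrX:166427825-166429358 (8.03 and 7.73). All but chr8:13785174-13786680 still had a peak in WT replicate 2 at 72 h. The densest windows were chr7:52702370-53185482 (29 of 38), chr10:80599827-81090660 (28 of 53) and chr7:134148034-134632286 (26 of 37). Neighbours within 50 kb were found for 69.1% against 66.5% for random draws (permutation p = 1e-04), a difference that was not past the threshold at 200 kb (p = 0.415). Regions found only at 72 h were again led by chrX:47952692-47953850 (fold 19.6 and 27.6), chrX:47955441-47956710 (15.7 and 36.2), chrX:47967483-47968386 (17.6 and 26.7), chrX:47964800-47965771 (15.1 and 16.9) and chrX:100676541-100677557 (10.3 and 12.8). Their densest windows were chrX:47903051-47976746 (10 of 11), chrX:72978864-73004678 (4 of 4) and chr15:61239614-61502444 (2 of 4). The X chromosome held 16 of the 46 (34.8%, against 2.47% of the other regions, adjusted p = 8.79e-13, Fisher's exact test), and 30.4% of the 46 had a neighbour within 50 kb against 0.492% for random draws (permutation p = 1e-04). Of the 16, the X windows above held 10 and 4, so the regions are not independent and both results rest largely on these windows. Neighbours were not tested without the X chromosome. The count at 72 h was 165 without DKO 72 h replicate 1 and 30 without the X chromosome.

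X chromosome regions present in all 8 libraries also held a different place in the lists at each time. The median rank percentile of these 228 regions lay below that of autosomal regions by a difference of -12.7 and -15.5 points in WT at 0 h and -14.0 and -13.7 in DKO at 0 h. At 72 h the difference was -5.80 and -4.63 points in WT and -5.81 and -9.46 in DKO, so each of the 4 libraries at 72 h lay nearer to 0 than each of the 4 at 0 h.

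**Figure D5:**
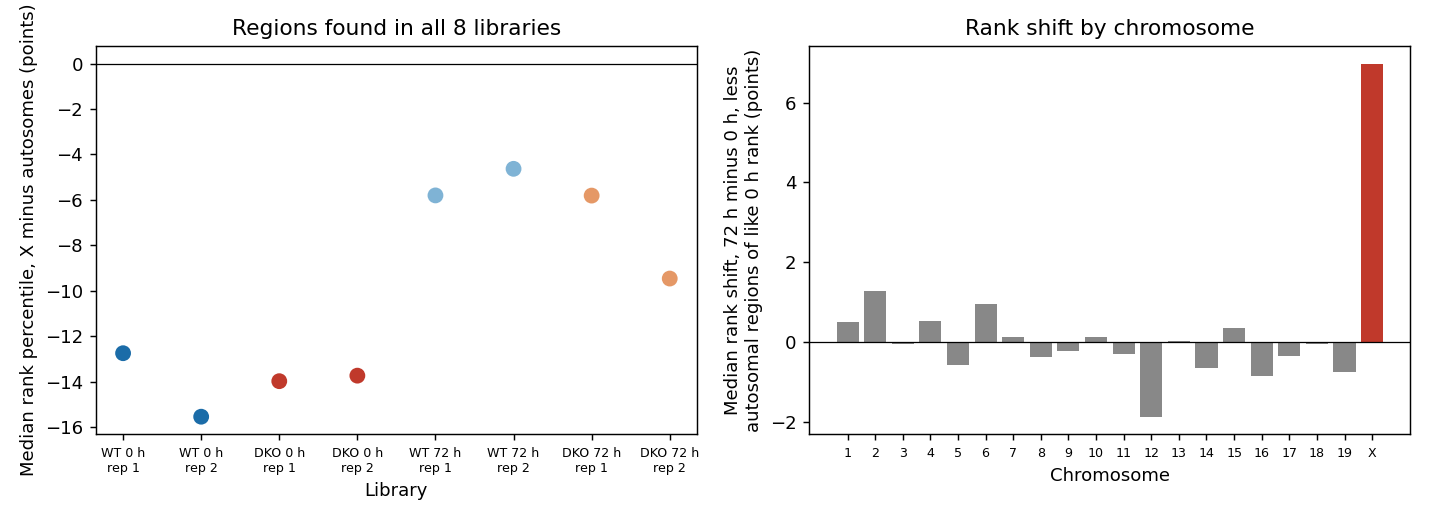
Left, median rank percentile of X chromosome regions minus that of autosomal regions (points, vertical axis) in each of the 8 libraries, over regions found in all 8. Right, median rank shift from 0 h to 72 h of each chromosome's regions, less autosomal regions of like rank at 0 h (points, bars), which is 6.98 for the X chromosome and between -1.88 and 1.27 for the autosomes.

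Whether regions found in WT only at 72 h were also found in DKO cells was tested against WT regions of like rank that were present at both times. Of the 228 regions, 21.5% (exact 95% interval 16.3 to 27.4) had a peak in DKO 72 h replicate 1 and 41.2% (34.8 to 47.9) in replicate 2. Rank-matched shared regions were found at 31.6% and 65.9%, differences of -10.1 points (permutation test over regions, p = 6e-05) and -24.6 points (p = 1e-05, the smallest possible). Without WT 72 h replicate 1 the differences were -3.66 and -14.6 points, with the smallest possible p for both. In all, 130 of the 228 (57.0%) had no peak in either DKO library at 72 h. In the other direction, 91.3% and 93.5% of the 46 DKO regions were found in WT replicates 1 and 2, against 95.3% and 99.7% of matched regions (-3.98 points, permutation p = 0.341, and -6.23 points, p = 0.00124). Other settings redefined the regions, which numbered 31 at −log10 q of at least 5, 754 with lists of equal length and 318 with summits within 100 bp. At −log10 q of at least 5 the differences were 0.874 and 0.291 points (permutation p = 1 for both). With lists of equal length they were -17.2 and -19.4 points and with summits within 100 bp -25.6 and -39.2 points (permutation p = 1e-05 for each). In WT replicate 1 the difference was -18.4 points without DKO 72 h replicate 1, -10.7 without DKO 72 h replicate 2 and -6.34 without DKO 0 h replicate 2, and in WT replicate 2 it was -10.1 without DKO 72 h replicate 1. At equal length the differences for WT regions looked up in DKO were -18.2 and -21.5 points, and the difference between the directions was not tested. The intervals cover counting error only, and regions are not independent replicates.

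The 228 regions were chosen on the same WT lists, which favours WT. When regions were chosen on WT replicate 2 alone (1627 regions), 14.0% had a peak in WT replicate 1 and 9.65% in DKO replicate 2 at 72 h, against 70.6% and 66.6% of shared regions (odds ratio 1.31, 95% interval 0.964 to 1.78; Fisher's exact test, p = 0.0973). This comparison of WT replicate 1 with DKO replicate 2, which was not matched on rank, was not past the threshold. The matched test of the same 1627 regions, given above, was past it but was run in DKO only. Since WT replicate 1 also fell short of unmatched shared regions and was not tested against matched ones, the shortfall in DKO alone does not show a difference between genotypes. A set of 31 regions was found in all 4 libraries at 72 h and none at 0 h, and 16 of these lay on the X chromosome. Among the 1189 regions with no peak in any 0 h library, 165 were found in both WT and 35 in both DKO libraries at 72 h, for which independent lists would share 4.86.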

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

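Of the tests in this part, that of lower enrichment, that of relative depth, that of the 72 h fate of 0 h regions and the count of other splits were chosen after the result was seen, as was the definition on a single library. The permutation test of regions found only at 72 h was planned.

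The regions that WT cells had only at 72 h stood out because they were found less often in DKO cells than WT regions of like rank, by -10.1 points in DKO replicate 1 and -24.6 points in replicate 2. Without WT 72 h replicate 1 these differences were -3.66 and -14.6 points. The 46 regions that DKO cells had only at 72 h were found less often in WT replicate 2, by -6.23 points. With peaks of −log10 q of at least 5, which left 31 such regions, the difference turned to 0.291 points (permutation p = 1). With lists of equal length, which gave 754, it was -19.4 points (permutation p = 1e-05). With the regions chosen on WT replicate 2 alone, an unmatched comparison of WT replicate 1 with DKO replicate 2 gave an odds ratio of 1.31 (95% interval 0.964 to 1.78). Of these regions, 14.0% had a peak in WT replicate 1 and 9.65% in DKO replicate 2 at 72 h, against 70.6% and 66.6% of shared regions. A shortfall from unmatched shared regions was thus not particular to DKO cells. Whether WT replicate 1 also fell short of rank-matched regions was not tested. Peaks on chromosome Y, which no comparison used, were listed in WT 0 h replicate 1 (2 peaks), WT 0 h replicate 2 (1 peak) and DKO 0 h replicate 2 (2 peaks), with folds from 4.28 to 4.87, the IgG list held 0 there and no library at 72 h listed one.

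The 72 h libraries held fewer peaks than the 0 h libraries. If all libraries were called against 1 shared control, fewer reads at 72 h were argued against by the relative depth, with a ratio of means of 1.46. That control was assumed, and without it the ratio decides nothing. WT 72 h replicate 2 (1.76) lay below both WT 0 h libraries (1.88 and 1.96). Lower enrichment over the whole library may account for the shorter lists: 0.722% of the WT regions found only at 0 h lay in the top 25% of the regions found in both WT libraries at 0 h (0.897% in the top 25% of the peak lists themselves), where randomly drawn regions would have 25% of their number. The same share is what a real reduction of binding at weak sites would give, and stimulation with cytokines stays open as an untested biological explanation.

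The X chromosome was over-represented among regions found only at 72 h in both genotypes. If the 0 h cells came from male and the 72 h cells from female animals, X regions would rise in rank as a whole, and over the 228 X regions found in all 8 libraries the rank shift from 0 h to 72 h exceeded that of autosomal regions by 6.64 percentile points, while single autosomes ran from -2.27 to 1.45 (permutation test of 10000 draws of regions, p = 1e-04, the smallest possible). Chromosome Y peaks were listed in 3 of the 4 libraries at 0 h and 0 of the 4 at 72 h. Each of those 3 had a peak within chrY:346387-347038, which male cells at 0 h would give, but DKO 0 h replicate 1 listed none. Their absence at 72 h decides nothing, since their folds of at most 4.87 were near the minimum of 4. The weakest decile of WT 0 h replicate 1 peaks was found at only 0.952% to 28.9% in the libraries at 72 h. The rank shift is consistent with a difference in sex between the times, a hypothesis found and tested on the same libraries. The effect of cytokines on the X chromosome cannot be told apart from it, because 0 libraries had a sex given in the labels used here. If the sexes did differ, every comparison of 0 h with 72 h given here would hold that difference too.

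WT-only regions outnumbered DKO-only regions at 0 h. With lists of equal length the ratio was 1.36, below the 1.5 set as evidence against list length but not low enough to show that length was the cause, so part of the excess may come from it. Library quality at 0 h alone was argued against only for regions with a peak in just 1 of WT replicate 1 and DKO replicate 2 at 72 h. These followed their 0 h genotype with an odds ratio of 26.2. They were 211 and 19 of the 1932 WT-only regions and 14 and 33 of the 1080 DKO-only regions, and the rest were not covered. In WT replicate 2 at 72 h, which had a longer list, 17.1% of the DKO-only regions had a peak, against 1.85% and 5.46% in the DKO libraries. Loss of Tcf1 and Lef1 stays open as the biological explanation, as do other differences between the mice of each genotype, which were not tested.

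For the 197 regions found in all 4 WT and no DKO library, 5 of the 35 splits of the 8 libraries gave as many, so chance was not excluded by this count, and the highest other split gave 2973. That split was the one of 0 h against 72 h, and the other 3 joined 3 of the 0 h libraries with WT 72 h replicate 2 (236, 318 and 400 regions), which points to a structure of the samples by time and list length. Among the 18 splits that keep 2 libraries of each time on each side, 1 gave as many, the real one, and the highest other gave 16. This gives an exact p over splits of 0.0556, the smallest possible here. These splits were added after the data were seen, so they do not exclude chance either.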

How the results depend on the processing

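Over 28 results, 221 alternatives were computed: 166 kept the direction and the side of the threshold or stayed near the value, 45 moved, 5 newly passed a threshold, 3 no longer passed it and 2 reversed. Near meant within a factor of 1.5 for counts and within the SD between the directions for replicate overlap. That SD was wide at 72 h, so replicate overlaps of 64.9% in WT and 62.8% in DKO with summits were counted as near. Counts of specific regions depended on list length, absolute depth is unknown, and an absent peak shows only that none was called. Autosomes alone and the pair of nearest list length were chosen after seeing the data. Where a setting asks for fewer libraries or shortens lists, its construction moves the counts; elsewhere the cause was not tested.

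With lists of equal length, genotype at 72 h gave 461 WT-only and 423 DKO-only regions, time in WT 1211 at 0 h and 1075 at 72 h, time in DKO 987 and 754, and genotype over both times 54 WT-only and 30 DKO-only. With a peak in at least 1 library, genotype at 0 h gave 4575 and 4042, genotype at 72 h 10387 and 162, time in WT 9698 and 1642, and time in DKO 17924 and 176. With summits within 100 bp, replicate overlap was 74.8% in WT and 70.3% in DKO at 0 h and 64.9% and 62.8% at 72 h, DKO-only regions at 72 h numbered 156, regions found only at 72 h 608 in WT and 318 in DKO, and DKO-only regions over both times 13. At −log10 q of 5 or more, 6 regions were DKO-only at 72 h. The pair of nearest length gave 2837 WT-only and 1749 DKO-only regions at 72 h, and autosomes alone 30 regions found in DKO only at 72 h. The excess of neighbours over random draws was 0.118 points at 10 kb and 1.78 at 200 kb for WT-only regions at 72 h, and 0.176 at 200 kb for DKO regions found only at 0 h.

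For WT regions found only at 72 h and looked up in DKO, the difference from shared regions stayed below 0 and past the threshold in each alternative run of the matched or unmatched permutation test. It was -18.2 and -21.5 points in DKO replicates 1 and 2 with equal lengths, -38.4 and -44.1 without matching, and from -13.4 to -3.66 and from -29.5 to -14.6 with a library left out, the smallest without WT 72 h replicate 1. An unmatched shortfall was also seen in WT replicate 1 for regions chosen on WT replicate 2 (14.0% against 70.6%), and a matched one was not tested there. A shortfall in DKO alone therefore does not show a difference between genotypes. In both directions the regions were redefined at each setting apart from the one without matching. For DKO regions found only at 72 h and looked up in WT, the difference from shared regions reversed at −log10 q of 5 or more, to 0.874 points in replicate 1 and 0.291 in replicate 2 (permutation p = 1 for both). In replicate 1 it was -17.2 points with equal lengths, -25.6 with summits, -6.67 without matching, and from -18.4 to -5.42 with a library left out. In replicate 2 it was -19.4 with equal lengths, -39.2 with summits, -6.39 without matching, and from -10.1 to -4.91 with a library left out.

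Leaving out each library in turn gave 2782 to 3550 WT-only and 1627 to 2864 DKO-only regions at 0 h, and 2665 to 10218 and 17 to 208 at 72 h. Time in WT gave 5301 to 11905 regions found only at 0 h and 243 to 1627 only at 72 h, time in DKO 57 to 165 only at 72 h, and genotype over both times 198 to 738 WT-only and 5 to 15 DKO-only. The DKO minus WT difference in peaks ran from -7992 without WT 72 h replicate 1 to -900.9 without DKO 72 h replicate 1, where leaving out a library also unbalances the times.

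Replicate numbers were not treated as pairing the samples, since the labels used here state no pairing and not every correlation was above 0.1, which does not exclude a shared batch or day. Deviations from group means correlated at 0.0484 and 0.181 between genotypes and 0.0180 and 0.0159 between times. With the number as a block, the peak differences stayed at -13678.8 (exact p = 0.125) and -4810.75 (exact p = 0.25), and the counts of 197 and 5 regions were unchanged by construction, with 1 of 8 block splits as large and 13 the highest other.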

Other observations

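Further regions were shared by both genotypes at 72 h. Of the 31 regions with a peak in all 4 libraries at 72 h and none at 0 h, the 15 autosomal ones were led by chr11:95609478-95610147 (fold 9.64 and 17.4 in WT, 8.58 and 14.5 in DKO), chr11:61961845-61962568 (12.1 and 17.2, 9.14 and 10.6) and chr15:61239614-61240510 (13.1 and 14.2, 5.12 and 11.4). The X chromosome held 51.6% of the 31, against 2.46% of the other regions (Fisher's exact test, chosen after the X regions were seen, odds ratio 42.3, p = 4.28e-18). Most of these X regions lay within chrX:47903051-47976746 and chrX:72978864-73004678, so they are not independent and the p-value is too small. In the other direction, 2973 regions had a peak in all 4 libraries at 0 h and none at 72 h, and 79 of these lay on the X chromosome.

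Some regions that WT cells had only at 72 h had a peak in DKO libraries at 0 h. These shares were not tested against other regions, and a peak absent from WT at 0 h may be one that was not called. Of the 228 regions, 21.5% had a peak in DKO 0 h replicate 1 and 23.2% in DKO 0 h replicate 2. Of the 46 regions that DKO cells had only at 72 h, 21.7% and 17.4% had a peak in WT 0 h replicates 1 and 2. The regions chr1:167788481-167792284 and chr4:119593485-119594161 ranked above the other DKO-only regions over both times, with a mean rank percentile of 99.8 and 76.3 over the DKO lists, and the next, chr10:128100606-128101166, had 41.9. The 5 leading WT-only regions over both times had 78.8 to 84.1 over the WT lists.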
